A study of Mus musculus with 8 samples.

How the data were processed

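The series holds 8 arrays of mouse skin, 4 labelled NcstnΔKC and 4 labelled normal, with replicate numbers 1 to 4 in each group, taken from the sample titles. Each array was hybridised with Cy3-labelled total RNA, per the labels, so there is 1 colour per array. Per the labels' protocols, RNA was extracted with a mirVana kit, its integrity was checked on a Bioanalyzer and it was labelled with Agilent's miRNA labelling kit. Per the file headers, the images were read by Agilent Feature Extraction 10.7.1.1, which gives for each spot a raw mean intensity, a local background intensity and a processed intensity after subtraction of a fitted background surface (spatial detrending on), with no normalization between arrays. The same software gives a total signal per miRNA, in which undetected probes are left out or set to an error value, and flags for detection, saturation and outliers. The positions in these files refer to mouse build mm9, per the file headers. The deposited series matrix holds log2 values of the same arrays with medians of 3.24, 3.24, 3.25 and 3.25 (normal 1 to 4) and 3.24, 3.25, 3.25 and 3.25 (NcstnΔKC 1 to 4). These correlated across miRNAs with log2 of the software's total signal (r from 0.883 to 0.909); how they were normalized and centred is not given in the sources used here.

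Every array has 58594 spots, of which 56430 belong to 4415 probes for 1881 miRNAs and 2164 are controls. Control spots were left out, as were spots marked as outliers (2223 to 2940 per array). No spot was saturated (0 on every array). A probe counted as detected where at least 50% of its spots were well above background, and a miRNA where at least 1 probe was. Detection ranged from 198 to 273 miRNAs per array (10.5% to 14.5%), so the scaling used the 301 probes detected on all 8 arrays. The mean processed intensity of each probe was divided by the array's 75th percentile over those probes, probes were summed per miRNA, values under a floor of 0.0318 (log2 -4.97) were set to it, and log2 was taken. The floor is the median over arrays of the lowest scaled signal of a detected miRNA. The 222 miRNAs detected on all 4 arrays of at least 1 group were tested, 18 of them with at least 1 value at the floor. The floor understates their change and, where several values of a group sit at it, also their spread, which can lower p. Of 170 tested miRNAs with at least 2 probes detected on 4 or more arrays, 4 had probes of opposite direction (let-7i-5p, miR-199b-5p, miR-342-3p and miR-721), 0 of them among the 64 changed ones.

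Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit on group alone and eBayes, prior degrees of freedom 2.46), with Benjamini-Hochberg adjustment over the 222 miRNAs and a threshold of 0.05. Differences are NcstnΔKC minus normal on the log2 scale. Lists of miRNAs with at least 3 tested members (18 of 26) were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were the alternatives; fry asks whether members move one way on balance and does not set them against other miRNAs. Single values per array were compared by exact two-sided permutation over the 70 labelings. The design, the lists, the alternatives and the rule for named miRNAs were chosen before the data were examined. The rule took, among changed miRNAs with non-overlapping groups, the 10 largest rises and the 10 largest falls, then up to 4 members of each list with the smallest p, then miR-30a-3p and miR-30a-5p, on which the study's later published work centres. Had fewer than 10 passed, the 10 with the smallest p would have been named.

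The lists were epithelial miRNAs (miR-203, miR-205 and the miR-200 family), the miR-30 family, inflammation-induced, white blood cell, red blood cell, striated muscle, endothelial, fibroblast and smooth muscle, adipose, neural and Schwann cell and pigment cell miRNAs, hair cycle regulators, hypoxia and stress miRNAs, the Dlk1-Dio3 imprinted cluster, the miR-29, miR-34 and let-7 families, and the miR-17 to miR-92 clusters. Further lists were the miR-466, miR-467 and miR-669 family, GC-rich late-numbered miRNAs, the miR-23, miR-24 and miR-27 clusters, the miR-99, let-7 and miR-125 cluster partners, the miR-10 and miR-196 Hox cluster, the miR-183 cluster, the miR-15 and miR-16 family, and the miR-130, miR-148 and miR-152 family. Some miRNAs stand in more than 1 list, and most are expressed in several skin cell types.

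The alternatives were other scalings (percentile over all probes, quantile, cyclic loess, none, and spike-in scaling on 4 control RNAs, the last added after the data were seen), normexp background correction with an offset of 50, the software's totals, the brightest probe, the mean of log2 values over probes, the series matrix values, other floors, other filters on dim miRNAs, the software's detection call, a replicate block, array weights, a trended robust eBayes, a 2-fold threshold, and leaving out each array in turn. The fit was tested on simulated data for this comparison (222 miRNAs, 8 arrays, 50 runs with 60 changed miRNAs each). It called 39.6% of 1.5-fold, 76.5% of 2-fold and 95.7% of 4-fold changes, with 4.07% false calls, and a list raised 2-fold was called in 100% of runs with 0.02 other lists per run. The simulated noise was independent between miRNAs, while members of a list here had estimated residual correlations of up to 0.946. The rates for lists therefore need not hold for these data. Normal noise, with SDs taken from the fit itself, was added to log2 means of miRNAs that had passed the filter. Background correction, scaling, the floor and the detection filter were not simulated. The rates per miRNA thus test the fit alone and do not cover those steps, on which the calls depend. Replicates of 1 group correlated over the tested miRNAs with r from 0.915 (normal 2 and 3) to 0.995 (NcstnΔKC 3 and 4), and no pair held identical values (median absolute log2 difference at least 0.14), so all 8 arrays were kept as separate samples; whether any pair shares 1 RNA is not settled by these values. Hairpin names and neighbours came from the GRCm38.p6 gene table (221 of 222 tested miRNAs matched), with no coordinates taken from it, and 123 of 222 have a position in the scanner files. Matching was by name, and some miRNAs with several hairpins were matched to only 1 of them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.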

Results

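Mature miRNAs were measured in skin of male mice that carry floxed alleles of Ncstn and the Krt14-CreER transgene. Ncstn encodes nicastrin, a subunit of the γ-secretase protease that cleaves Notch receptors, and Krt14-CreER places a tamoxifen-activated Cre recombinase under the promoter of a keratin of basal keratinocytes. The NcstnΔKC group (4 samples) received tamoxifen by gavage from 8 weeks of age, at 20 mg per kg per day on 5 days in a row and then every 10 days. The normal group (4 samples) had the same genotype and received corn oil, so tamoxifen and loss of Ncstn differ together between the groups. Skin was excised at 16 weeks, and each RNA was hybridised to a 1-colour array that carries probes for 1881 mouse miRNAs. These arrays do not measure Ncstn mRNA, so the deletion was not checked here. Nothing in the labels says whether the samples of a group came from separate mice, so the p-values measure the spread between these samples, which may be partly technical. Arrays are named here by group and replicate, as normal 1 to 4 and NcstnΔKC 1 to 4.

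The normal arrays detected 252 ± 17.2 miRNAs and the NcstnΔKC arrays 217 ± 17.2 (mean ± SD, n = 4 each; exact two-sided permutation p = 0.0571, where 0.0286 is the smallest these 8 arrays can give). The difference of -34.5 miRNAs thus did not pass the threshold. Single arrays ranged from 198 (NcstnΔKC 2) to 273 (normal 2) detected miRNAs, and the number of arrays limits the precision of every comparison. The 5 brightest miRNAs held 37.1 ± 2.40% of the summed signal on normal arrays and 44.3 ± 1.16% on NcstnΔKC arrays (n = 4 each, exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.103 over 18 array measures). The percentile used for scaling was 1259 ± 44.6 on normal and 1053 ± 98.3 on NcstnΔKC arrays (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.103). Scaling thus raised NcstnΔKC values relative to normal ones. All 8 arrays lie on 1 slide, with every normal array in slide row 2 and every NcstnΔKC array in slide row 1, so slide row and group cannot be told apart.

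The comparison of NcstnΔKC with normal skin asks which miRNAs differ in abundance between them. In NcstnΔKC skin miR-21a-5p, known to be abundant in inflamed and proliferating tissue, was 5.70-fold higher, going from a scaled log2 level of 2.38 ± 0.24 in normal skin to 4.90 ± 0.40 (SD, n = 4 each). Other miRNAs higher in NcstnΔKC skin included miR-511-3p, whose hairpin lies within the macrophage mannose receptor gene Mrc1 (5.11-fold), miR-146b-5p (3.11-fold), miR-142a-3p, abundant in blood cells (2.86-fold), miR-155-5p (2.39-fold), and all 10 tested members of the miR-17 to miR-92 clusters. Lower in NcstnΔKC skin were miR-494-3p (4.11-fold), miR-204-5p (3.22-fold), miR-195a-5p (2.31-fold), miR-30a-3p (2.32-fold) and, by smaller amounts, the epithelial miRNAs miR-203 and miR-429-3p (1.76-fold). Of 222 miRNAs tested, 95 passed an adjusted p of 0.05, 33 of them higher and 62 lower. In 78 of the 95 the groups did not overlap, as in 82 of all 222 tested (36.9%, against 2.86% by chance).

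The median log2 difference of all tested miRNAs was -0.23, so changes are also given relative to it. For miR-21a-5p the log2 difference was 2.51 ± 0.23 (SE, adjusted p = 0.000477), or 2.75 relative to that median, with all 4 NcstnΔKC values above all 4 normal values. Its probes target chromosome 11, 86397588 to 86397607 (mm9), and its hairpin lies within the span of the gene Vmp1 in the GRCm38.p6 annotation. The log2 difference of miR-511-3p was 2.35 ± 0.36 (adjusted p = 0.00238). The other large rises with separated groups were miR-1949 (3.2-fold, adjusted p = 0.00147), miR-18a-5p (3.21-fold, 0.00404) and miR-362-3p (2.66-fold, 0.003). A miRNA detected on no array of a group has only a bound there, so its fold is given as at least the detected group's mean over the higher of each array's lowest detected signal and the miRNA's own. Such bounds hold only under the main scaling and background correction. On that basis miR-7014-5p was at least 4.50-fold and miR-17-3p at least 2.30-fold higher (both adjusted p = 0.00166). Over the 7 scalings other than the percentile over all probes their log2 differences ran from 0.84 to 2.79 and from 0.41 to 2.01. All 4 normal values of miR-677-3p were set to the floor, against which it was at least 2.51-fold higher (adjusted p = 0.000477). With a floor 2 times as high its adjusted p was 0.0659, in a range over all alternatives from 1.2e-05 to 0.199. With the scanner software's totals, which leave out undetected probes or give them an error value, miR-17-3p turned to -0.017 and miR-677-3p to -0.46. The difference of miR-5099 was larger, 2.74 ± 0.79 (adjusted p = 0.0249), but its groups overlapped; it was picked out after its values were seen, and its call was lost without normal 2, normal 3, NcstnΔKC 3 or NcstnΔKC 4 (adjusted p up to 0.0698).

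Among the falls, miR-494-3p of the Dlk1-Dio3 imprinted cluster had a log2 difference of -2.04 ± 0.28 (adjusted p = 0.00173, -1.80 relative to the median of tested miRNAs) and was the only tested one of that list's 91 on the array. Not in the list, but with hairpins also on chromosome 12, miR-3072-5p (within Mirg) and miR-1906 (within Meg3) were called lower too. These calls were kept in 5 and 3 of the 7 scalings other than the percentile over all probes. miR-204-5p, of an intron-hosted hairpin within Trpm3 and present in pigmented epithelia, fell by 1.69 ± 0.24 on the log2 scale (adjusted p = 0.00182) and was detected on 1 NcstnΔKC array. Its log2 difference ran from -1.85 to -0.33 over the 7 scalings other than the percentile over all probes. The other pigment cell miRNA tested, miR-211-3p, differed by 0.80 ± 0.64 (adjusted p = 0.338). Among miRNAs with little known function, miR-6908-5p was 3.28-fold lower (adjusted p = 0.00182) and miR-3098-5p 2.65-fold lower (0.00545), the first turning to 0.55 with the scanner software's totals. miR-1897-3p was at least 4.04-fold lower (0.00238), miR-6944-5p at least 3.2-fold (0.00424) and miR-6969-5p at least 3.19-fold (0.00272). Over the 7 scalings other than the percentile over all probes their log2 differences ran from -2.32 to -0.76, from -1.86 to -0.36 and from -1.88 to -0.36. The calls of miR-7070-5p (-1.49, adjusted p = 0.0351) and miR-671-5p (-1.45, adjusted p = 0.0207) were weaker. The first was lost without normal 4 or NcstnΔKC 1, 2 or 3 (adjusted p up to 0.0878) and the second without NcstnΔKC 3 (0.0578). Both were also lost with cyclic loess, normexp and the series matrix values, with log2 differences of -1.79 to -0.46 and of -1.75 to -0.12 over the 7 scalings other than the percentile over all probes.

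**Figure D1:**
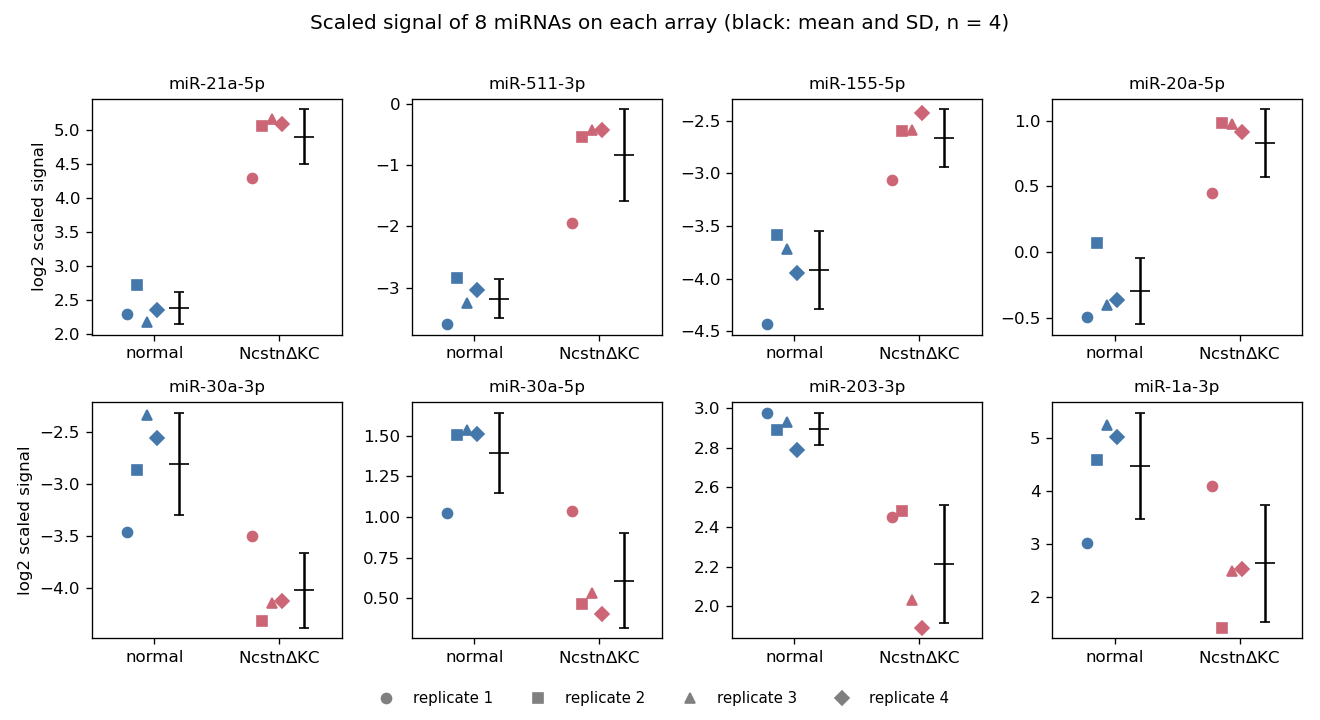
Scaled log2 signal of 8 miRNAs on each of the 8 arrays (points), with the mean and SD of each group of 4. The 4 NcstnΔKC values of miR-21a-5p, miR-511-3p, miR-155-5p and miR-20a-5p all lie above the 4 normal values, while those of miR-1a-3p and miR-30a-5p overlap the normal ones; the fall of miR-30a-5p and miR-203-3p turns into a small rise when arrays are scaled by the percentile over all probes.

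The miR-17 to miR-92 clusters, whose members are known to rise in proliferating cells, moved as a group. All 10 tested members, of 29 on the array, were higher, over all miRNAs tested and adjusted over the list alone, with a mean log2 difference of 1.0 and groups that did not overlap in any of the 10. The untested members were not detected on all 4 arrays of either group. miR-17-3p, detected on no normal array, was tested only because all 4 NcstnΔKC arrays detected it. With the percentile over all probes 1 of the 10 passed, and with spike-in scaling 5. Their mean lay 1.23 above that of the other miRNAs (limma camera, adjusted p = 2.35e-07), but adjusted p = 0.480 with an estimated correlation between members; over all alternatives with camera that p ran from 9.13e-09 to 0.480. Examples were miR-20b-5p (2.24-fold, adjusted p = 0.00204), miR-20a-5p (2.18-fold, 0.003), miR-19b-3p (2.05-fold, 0.00307) and miR-92a-3p (1.72-fold, 0.00456). The probes of miR-20a-5p target chromosome 14, 115443410 to 115443427, and those of miR-20b-5p the X chromosome, 50095305 to 50095323 (mm9). miR-20a-5p, miR-20b-5p and their relatives, and miR-19a-3p and miR-19b-3p, differ in few bases, so how much of their signal each holds is uncertain. From the third cluster, within Mcm7, miR-106b-5p (1.63-fold), miR-93-5p (1.54-fold) and miR-25-3p (1.40-fold) rose as well. The list mean stayed positive under all 8 scalings, from 0.65 to 1.80. Without NcstnΔKC 3 the number of calls was 8: miR-25-3p (adjusted p = 0.0661) was lost there, and miR-19a-3p there and without normal 4 (up to 0.0554).

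Of 5 tested miRNAs known to be induced in inflammation, 3 rose and 0 fell, with the same count adjusted over the list alone. They were miR-21a-5p, miR-146b-5p (log2 difference 1.64 ± 0.29, adjusted p = 0.00402), which represses signalling through Toll-like receptors, and miR-155-5p (1.26 ± 0.22, adjusted p = 0.00402), which is induced in activated macrophages and lymphocytes and turned to -1.12 with the scanner software's totals. The closely related miR-146a-5p differed by -1.08 ± 0.52 (adjusted p = 0.131). Without NcstnΔKC 1 it was a fall (-1.58, adjusted p = 0.0124, in a range over all alternatives from 0.000691 to 0.892). miR-212-3p differed by 0.65 ± 0.34 (0.157) and passed as higher without normal 2 and with cyclic loess. The list mean lay 1.20 above that of other miRNAs (camera adjusted p = 0.0378), but adjusted p = 0.462 with an estimated correlation; over all alternatives with camera that p ran from 0.00584 to 0.462. It was 0.128 without NcstnΔKC 1 and 0.0578 without NcstnΔKC 2, and the list mean stayed positive under all 8 scalings.

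Among 6 tested white blood cell miRNAs, 1 rose, 1 fell and 4 did not pass (camera adjusted p = 0.517); adjusted over the list alone 3 were higher and 1 lower. The rise was in miR-142a-3p (log2 difference 1.52 ± 0.33, adjusted p = 0.00792). miR-223-3p, abundant in neutrophils, differed by 1.15 ± 0.44 (adjusted p = 0.0644), miR-150-5p of mature lymphocytes by 0.89 ± 0.34 (0.0653) and miR-342-3p by -0.00 ± 0.18 (0.999). miR-181b-5p was at least 1.80-fold lower (0.037), a call lost without normal 1, 2 or 4 or NcstnΔKC 1, 3 or 4 (adjusted p up to 0.104) and turned to 0.12 with the percentile over all probes. The list's mean of 0.40 stayed positive under all 8 scalings. Of the red blood cell miRNAs, miR-486a-5p was lower (-1.91 ± 0.54, adjusted p = 0.0229) and miR-451a differed by 0.53 ± 0.49 (0.392). The call of miR-486a-5p was lost without normal 3 or 4 or NcstnΔKC 2, 3 or 4 (adjusted p up to 0.0668) and with quantile normalization, cyclic loess, normexp and the series matrix values, and its log2 difference ran from -2.08 to -0.56 over the 7 scalings other than the percentile over all probes. The endothelial miR-126a-3p differed by 0.15 ± 0.14 (adjusted p = 0.392).

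Of 8 tested epithelial miRNAs, 5 fell and 3 did not pass (camera adjusted p = 0.609), and the list mean of -0.35 turned to 0.52 with the percentile over all probes. Adjusted over the list alone 5 were lower and 1 higher. miR-429-3p (log2 difference -0.81 ± 0.16, adjusted p = 0.00466), miR-200a-3p (-0.74 ± 0.18, 0.012) and miR-200b-3p (-0.58 ± 0.16, 0.0191) share a cluster of the miR-200 family, which holds cells in an epithelial state. miR-203-3p, which promotes differentiation of the epidermis, was 1.6-fold lower (adjusted p = 0.0139) and its partner arm miR-203-5p 1.78-fold lower (0.0139). With the percentile over all probes all 5 turned, miR-429-3p to 0.056, miR-200a-3p to 0.13, miR-200b-3p to 0.29, miR-203-3p to 0.19 and miR-203-5p to 0.039. The other cluster of the family did not pass, with miR-141-3p at 0.30 (adjusted p = 0.138) and miR-200c-3p at 0.12 (0.618), and the basal keratinocyte miRNA miR-205-5p differed by 0.47 ± 0.17 (0.0518). With quantile normalization, cyclic loess and normexp the list had 4 falls and 1 rise (miR-205-5p), and in the series matrix values 4 falls and 2 rises, the call of miR-203-5p being lost in all 4 settings. Without NcstnΔKC 3 the falls numbered 3: miR-203-3p was lost there (adjusted p = 0.053), and miR-200b-3p there and without normal 4 (up to 0.0554).

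In the miR-30 family 3 of 6 tested members fell, with 3 lower adjusted over the list alone as well (camera adjusted p = 0.517), and the mean of -0.46 turned to 0.42 with the percentile over all probes. With quantile normalization, cyclic loess and the series matrix values 1 fell, and with normexp 2. The study's later published work centres on miR-30a-3p and was built on these samples, so the family's count is not independent evidence of its direction. miR-30a-3p went from -2.80 ± 0.49 in normal skin, detected on 4 arrays, to -4.02 ± 0.36 in NcstnΔKC skin, detected on 1 (n = 4 each; log2 difference -1.22 ± 0.28, adjusted p = 0.00994). miR-30a-5p, from the other arm of the same hairpin, was brighter, at 1.39 ± 0.24 and 0.61 ± 0.29, and fell by 0.78 ± 0.19 on the log2 scale (adjusted p = 0.0137), with overlapping groups. Their probes target chromosome 1, 23279160 to 23279175 and 23279119 to 23279134 (mm9). The call of miR-30a-3p was lost with quantile normalization (adjusted p = 0.0623), cyclic loess (0.0566), normexp (0.111), the series matrix values (0.0506), the scanner software's totals (0.769), the percentile over all probes (0.835) and no filter on dim miRNAs (0.188), in a range over all alternatives from 0.000115 to 0.835. miR-30a-5p turned to 0.085 with the percentile over all probes and lost its call with no filter (0.173). miR-30c-5p (-0.57 ± 0.18, adjusted p = 0.0361) lost its call without normal 3 or 4 or NcstnΔKC 2, 3 or 4 (up to 0.0963) and with quantile normalization, cyclic loess and the series matrix values, and turned to 0.30 with the percentile over all probes, and miR-30d-5p, miR-30e-5p and miR-30b-5p differed by -0.17, -0.12 and 0.11.

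Striated muscle miRNAs had large differences and large spread: miR-1a-3p was 3.56-fold lower (log2 difference -1.83 ± 0.63, adjusted p = 0.0451) and the other 4 tested did not pass. miR-133a-3p differed by -1.73 ± 0.62 (adjusted p = 0.0518), miR-133b-3p, nearly identical in sequence, by -1.69 ± 0.62 (0.0557), miR-133a-5p by -1.84 ± 0.68 (0.0575) and miR-206-3p by -1.03 ± 0.73 (0.283). Adjusted over the list alone 4 were lower (camera adjusted p = 0.406). The list's mean of -1.62 stayed negative under all 8 scalings. Per array that mean was 0.61, 2.13, 3.09 and 2.66 in normal 1 to 4 and 1.86, -0.67, 0.39 and 0.42 in NcstnΔKC 1 to 4. The call of miR-1a-3p was lost without normal 2, 3 or 4 or NcstnΔKC 2, 3 or 4 (adjusted p up to 0.124). Leaving out normal 1 or NcstnΔKC 1 instead gave 4 falls, with miR-1a-3p at -2.31 in both (adjusted p = 0.0169 and 0.0159).

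**Figure D2:**
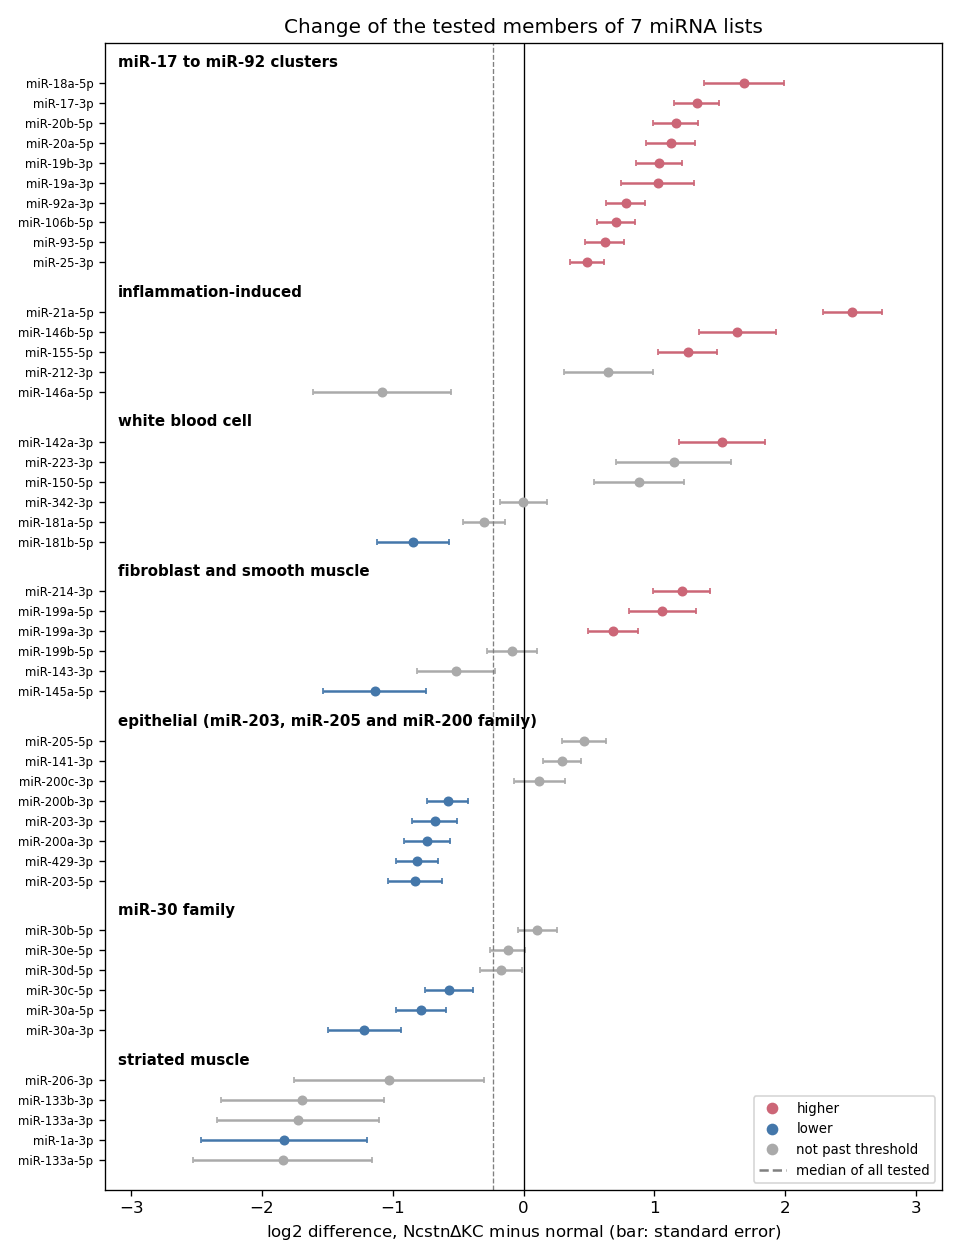
Log2 difference, NcstnΔKC minus normal, of each tested member of 7 miRNA lists (points; bars are ± SE, n = 4 per group), with a dashed line at the median of all tested miRNAs, -0.23. All 10 tested members of the miR-17 to miR-92 clusters lie above 0 under all 8 scalings, and the striated muscle members lie below the dashed line with wide error bars. The negative means of the epithelial and miR-30 lists turn positive with the percentile over all probes.

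Of 6 tested fibroblast and smooth muscle miRNAs, 3 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.406); the list mean of 0.20 turned to -0.05 with no scaling and -0.08 with spike-in scaling. miR-214-3p (2.31-fold, adjusted p = 0.00404) and miR-199a-5p (2.09-fold, 0.012), transcribed together from within Dnm3 in mesenchymal cells, rose in all 4 NcstnΔKC samples relative to all normal ones. miR-199a-3p (1.61-fold, 0.0227) lost its call without normal 3 or 4 (up to 0.0655). miR-145a-5p of smooth muscle was lower (-1.14 ± 0.39, 0.045), but not without normal 2, 3 or 4 or NcstnΔKC 2, 3 or 4 (up to 0.124) and not with quantile normalization, cyclic loess, normexp and the series matrix values (-1.34 to -0.15 over the 7 scalings other than the percentile over all probes), and its cluster partner miR-143-3p differed by -0.52 ± 0.30 (0.197). Of 3 adipose miRNAs, 2 fell, and 3 were lower adjusted over the list alone (camera adjusted p = 0.406); their mean of -0.84 turned to 0.03 with the percentile over all probes. miR-365-3p was 2.05-fold lower (adjusted p = 0.00766), miR-193b-3p 1.73-fold lower (0.0421; lost without normal 1, 3 or 4 or NcstnΔKC 1, 3 or 4, up to 0.108), and miR-378a-3p differed by -0.69 ± 0.27 (0.0659). The neural miR-128-3p was 1.86-fold lower (0.0236; lost without normal 4 or NcstnΔKC 2 or 3, up to 0.0682), while miR-338-3p differed by -0.15 ± 0.30 (0.685). With the percentile over all probes miR-193b-3p turned to 0.082 and miR-128-3p to 0.013.

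In the miR-15 and miR-16 family 2 of 6 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.932; mean -0.30, or 0.57 with the percentile over all probes). The falls were the clustered miR-195a-5p (2.31-fold, adjusted p = 0.00238) and miR-497a-5p (2.05-fold, 0.00466), which restrain cell cycle genes, whereas miR-15b-5p was 1.43-fold higher (0.0291; lost without normal 1 or 2 or NcstnΔKC 3 or 4, up to 0.0899). Among the miR-99, let-7 and miR-125 cluster partners 2 rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.932; mean -0.21, or 0.66 with the percentile over all probes). There miR-100-5p (2.10-fold, 0.00402) and miR-99a-5p (1.64-fold, 0.00972) were lower while miR-99b-5p was 1.52-fold higher (0.01). Likewise miR-125b-5p was 1.44-fold lower (0.0203; lost without normal 4 or NcstnΔKC 3 or 4, up to 0.0698). miR-125a-5p was 1.43-fold higher (0.0249; lost without normal 1 or NcstnΔKC 3, up to 0.0708). With the percentile over all probes miR-99a-5p turned to 0.15 and miR-125b-5p to 0.34. In the let-7 family 2 of 9 fell, also adjusted over the list alone, and 7 did not pass (camera adjusted p = 0.609; mean -0.22, or 0.65 with the percentile over all probes). They were let-7b-5p (1.69-fold, 0.00456) and let-7c-5p (1.54-fold, 0.00972), which turned to 0.11 and 0.24 with that percentile; let-7 sequences differ in few bases, so their separate values are uncertain.

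In the rodent miR-466, miR-467 and miR-669 family 5 of 7 fell, also adjusted over the list alone (camera adjusted p = 0.406; mean -0.81, or 0.03 with the percentile over all probes), and 4 fell without NcstnΔKC 3. Falls numbered 2 with quantile normalization, with cyclic loess (beside 1 rise) and in the series matrix values, and 1 with normexp (beside 1 rise; mean -0.06). Examples were miR-466h-3p (2.95-fold, adjusted p = 0.00457), miR-467f (2.40-fold, 0.00678, but 2.23 on the log2 scale with the scanner software's totals) and miR-466f-3p (at least 2.27-fold, 0.00466). The 16 tested GC-rich late-numbered miRNAs, many of them dim, gave 4 falls, 1 rise and 11 that did not pass, and 0 in either direction adjusted over the list alone. Their mean was -0.13, or 0.74 with the percentile over all probes, their median -0.01, and camera placed them above other miRNAs (adjusted p = 0.879), so the sign of the test differs from that of the mean and the median. The falls of miR-5112 (at least 2.05-fold, 0.0214) and miR-5107-5p (1.82-fold, 0.045) and the rise of miR-6366 (1.45-fold, 0.031) were each lost without NcstnΔKC 3 (adjusted p up to 0.0668, 0.112 and 0.0899); the first was also lost without NcstnΔKC 2, the second without normal 1, 2 or 4 or NcstnΔKC 1 or 2, and the last without normal 1 or 4 or NcstnΔKC 4. Without NcstnΔKC 3 none of the list's 5 calls was kept. With the scanner software's totals miR-5112 turned to 0.86 and miR-5107-5p to 4.99. In the miR-130, miR-148 and miR-152 family 2 of 3 fell, and 3 adjusted over the list alone (camera adjusted p = 0.406; mean -0.53, or 0.34 with the percentile over all probes). miR-152-3p (1.5-fold, 0.034) was lost without normal 1 or 2 or NcstnΔKC 1, 3 or 4 (up to 0.0899) and miR-130a-3p (1.29-fold, 0.0411) without normal 2, 3 or 4 or NcstnΔKC 2, 3 or 4 (up to 0.103), and the pair turned to 0.29 and 0.51 with that percentile.

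The remaining lists held few changes. Of 6 hair cycle regulators, 1 rose (miR-214-3p), 1 fell (miR-125b-5p, lost without normal 4 or NcstnΔKC 3 or 4, up to 0.0698) and 4 did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.609; mean 0.13 and median -0.08, or a mean of -0.13 with no scaling and -0.17 with spike-in scaling). In the miR-29 family miR-29b-3p was 1.47-fold higher (adjusted p = 0.0291; lost without normal 1, 2 or 4 or NcstnΔKC 3 or 4, up to 0.0668), also adjusted over the list alone, and 2 did not pass (camera adjusted p = 0.609; mean 0.08, or -0.18 with no scaling and -0.22 with spike-in scaling). In the miR-183 cluster miR-183-5p was 1.5-fold lower (0.0266; lost without normal 3 or 4 or NcstnΔKC 3 or 4, up to 0.0813), also adjusted over the list alone, but turned to 0.29 with the percentile over all probes, and 2 did not pass (camera adjusted p = 0.911; mean -0.19, or 0.67, 0.10 and 0.02 with the percentile over all probes, cyclic loess and normexp). None of the 5 tested miRNAs of the miR-23, miR-24 and miR-27 clusters passed, nor did any adjusted over the list alone (limma and camera; camera adjusted p = 0.609; mean 0.04, or -0.22 with no scaling and -0.27 with spike-in scaling); miR-27b-3p differed by 0.42 ± 0.17 (0.0806). Lists with fewer than 3 tested members had no list test: miR-34a-5p differed by -0.25 ± 0.17 (0.269), the hypoxia miRNA miR-210-3p by -0.27 ± 0.23 (0.357), and miR-10a-5p and miR-10b-5p of the Hox clusters by -0.10 ± 0.38 (0.812) and -0.18 ± 0.15 (0.347).

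The 222 tests used moderated limma statistics with Benjamini-Hochberg adjustment, and 54 of the 95 changed miRNAs differed at least 2-fold (19 higher, 35 lower). The split between rises and falls depends on the scaling: 34.7% of the calls were rises here, against 100% of 12 with the percentile over all probes, 52.9% of 68 with quantile normalization, 57.7% of 71 with cyclic loess, 56.3% of 64 with normexp, 50% of 72 in the series matrix values, 19.2% of 125 with no scaling and 16.5% of 109 with spike-in scaling. Among the miRNAs named here, the further calls lost with quantile normalization, cyclic loess, normexp and the series matrix values were those of miR-1a-3p, miR-128-3p, miR-152-3p, miR-181b-5p, miR-183-5p, miR-193b-3p and miR-466f-3p. That of miR-130a-3p was lost with quantile normalization, cyclic loess and the series matrix values, and those of let-7c-5p and miR-125b-5p with quantile normalization. That of miR-5107-5p was lost with quantile normalization, cyclic loess and normexp, that of miR-5112 with cyclic loess and normexp, and those of miR-466h-3p and miR-6944-5p with normexp. Of the rises outside the miR-17 to miR-92 clusters, miR-15b-5p, miR-29b-3p, miR-125a-5p and miR-199a-3p were lost with no scaling and with spike-in scaling, miR-99b-5p with spike-in scaling, and miR-6366 with all of these but normexp. Leaving out NcstnΔKC 3 gave 58 calls (23 higher, 35 lower), and 57 of the 95 calls, 22 higher and 35 lower, were kept whichever 1 of the 8 arrays was left out. Leaving out 1 array also added calls: without NcstnΔKC 1 these included miR-205-5p, miR-223-3p and miR-27b-3p (higher) and miR-29c-3p and miR-143-3p (lower). Without NcstnΔKC 2 miR-223-3p was added (higher), without normal 1 miR-378a-3p, without normal 2 miR-23a-3p, and without normal 3 or 4 miR-148a-3p (lower in each).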

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

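The tests on the miR-17 to miR-92 members, on the muscle miRNAs, on the label and the labelling of NcstnΔKC 1, and on the splits for the changed miRNAs and for the lists were chosen only after the result was seen.

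All 10 tested miR-17 to miR-92 members were higher in NcstnΔKC skin. Array scaling as the whole source is argued against by the smallest mean log2 change over 8 scalings, 0.65 (normexp background, SE over members 0.07). The members were correlated (estimated residual correlation 0.650), so that SE does not measure the spread between samples. Brighter hybridisation of all probes in the slide row that holds the NcstnΔKC arrays is argued against by the 4 dmr control RNAs, whose mean log2 ratio was 0.043 (SD 0.045) against 0.75 for the members without scaling, and by the median of all tested miRNAs without scaling, -0.49; but the control probes hur_1, hur_2 and hur_4 had log2 ratios of 0.30, 0.34 and 0.45, so an effect of the slide row on some probes cannot be told apart from the group. Near-identical sequences sharing signal within 1 seed subfamily are argued against as the whole source, since called members lay in 4 of 4 seed subfamilies. That count follows from all 10 being called, so it is not separate evidence. Sharing of signal within each subfamily stays open. White blood cells in the tissue also stay open, since that list had an adjusted p of 0.517 and a mean log2 change of 0.40, and a higher share of dividing cells in NcstnΔKC skin may also account for the rise, but was not tested.

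The striated muscle miRNAs had a mean log2 change of -1.62, with large spread within groups. Array scaling as the whole source is argued against only by the direction, which held over 8 scalings. The mean nearest to 0 was -0.76 (75th percentile over all miRNA probes, SE over members 0.15). That SE treats correlated members as independent, so it does not measure the spread between samples. With that scaling 0 of the 5 members passed, so scaling as the source is not excluded. A varying amount of muscle in the excised skin is a candidate explanation that the data are consistent with, since the members moved together within groups (estimated residual correlation 0.946). Whether less muscle lay in the NcstnΔKC samples by chance of excision or through the genotype was not tested.

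NcstnΔKC 1 stood apart from NcstnΔKC 2 to 4. Among 181 groups of 4 values examined there were 13 single-array deviations, not far above the 1 in 20 or so that chance gives. Many of the miRNAs examined move together, so the deviations are not independent. This array held 7 of the 13. It was below the other 3 NcstnΔKC arrays in miR-21a-5p (scaled log2 4.30), miR-20a-5p (0.45), miR-146b-5p (-1.76), miR-511-3p (-1.95) and miR-362-3p (-2.58), and above them in miR-146a-5p (-1.27) and miR-29c-3p (0.83). A wrong group label is argued against by its median position of 0.585 (quartiles 0.397 and 0.892) between the normal mean at 0 and the mean of NcstnΔKC 2 to 4 at 1, over 97 miRNAs called without it, and weak labelling or hybridisation of that array by 0 of 4 dmr control RNAs below the range of the other 7 arrays (dmr_6 lay above it, at 8862, and the bound was reworded from outside to below the range after that was seen). A varying amount of muscle in the excised skin cannot be told apart: with the muscle list left out the array was the lone extreme of its group at 5.34% of miRNAs, against 5.24% with it, but leaving out the 4 muscle miRNAs with no NcstnΔKC value at the floor could not have lowered that share enough to favour the explanation, so the bound written before the result was wrong; a milder response of this sample may account for its values and was not tested.

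Other values far from the remaining 3 of their group were let-7b-5p (3.92), miR-23a-3p (2.90) and miR-7070-5p (-1.05) in normal 2, miR-30a-5p (1.03) in normal 1, miR-193b-3p (0.13) in NcstnΔKC 2 and miR-5107-5p (-3.33) in NcstnΔKC 4. Of 5 kinds of probe named hur, present on every array and left out of the comparison, 2 were brighter on all NcstnΔKC arrays than on any normal array. The mean processed signal of hur_1 was 43273 against 35263 (ratio 1.23) and that of hur_4 was 4931 against 3615 (ratio 1.36). Both had an exact permutation p of 0.0286 (n = 4 each, the smallest these arrays can give), or 0.103 after adjustment over 18 array measures. The ratio was 1.27 for hur_2 (exact permutation p = 0.0571) and 1.03 for hur_6 (0.943), and hur_5 lay near background (-1.15 against -0.90, exact permutation p = 0.857). What these probes target is not given in the sources used here.

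Of the 35 splits of the 8 arrays into 4 and 4, the real one alone gave as many as 95 changed miRNAs. That is the fewest possible, so it argues against chance as the source of this count but cannot exclude it. The highest of the others, 14, came from the split that exchanges normal 1 and NcstnΔKC 1. The shifts of the miR-17 to miR-92 list (1.23, highest other 0.785) and of the inflammation-induced list (1.20, highest other 0.755) were each reached by 1 of 35 splits, the fewest possible. This decides nothing about chance, since these 2 of 18 lists were taken because they had passed in the real split, and with an estimated correlation their adjusted p was 0.480 and 0.462. Chance cannot be excluded for the number of lists past the threshold, 2, which 19 of the 35 splits reached, with 5 in the highest of the others.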

How the results depend on the processing

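Only spike-in scaling was chosen after seeing the data among these alternatives. In every fit with 1 array left out and under 7 scalings (75th percentile over detected probes, quantile, none, cyclic loess, normexp, spike-in and series matrix) 17 rises and 21 falls passed; of these, 6 falls turned with the percentile over all probes, where 0 of the 21 falls passed, and 4 rises and 2 falls with the scanner software's totals. Over those 7 scalings all 33 rises and 60 of 62 falls kept their direction, the exceptions being miR-1906 and miR-706, while 18 rises and 23 falls passed in all. With 1 array left out all 95 kept their direction, and the changed miRNAs numbered 58 to 97 in total (23 to 37 higher, 35 to 64 lower; lowest without NcstnΔKC 3), the lists past the threshold 1 to 2, the inflammation-induced shift 1.08 to 1.25 and that of the miR-17 to miR-92 clusters 1.17 to 1.32. Dim miRNAs limit the rest. The 75th percentile over all miRNA spots was 3.51 to 9.82, below the mean of the negative controls on every array (19.4 to 25.4, SD 9.30 to 10.6). The percentile over all probes was taken over probe means instead of spots and is not given here. It probably divides each array by a value at background level.

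For the changed miRNAs (total, higher and lower; 95, 33 and 62), the percentile over all probes gave 12, 12 and 0 (median shift 0.64), the scanner software's totals 52, 19 and 33, detection on all 8 arrays 61, 27 and 34 of 174 tested, no filter 19, 8 and 11 of 1881 tested, array weights 149, 52 and 97, and at least 2-fold 54, 19 and 35 by adjusted p or 59, 21 and 38 by unadjusted p. Falls numbered 32 with quantile normalization, 101 with no scaling, 30 with cyclic loess, 28 with normexp and 36 in the series matrix values, and rises 18 with spike-in scaling (91 falls). The percentile over all probes divides each array by 1 number, which moved most differences up together (median of all tested from -0.23 to 0.64). Its 0 falls by limma and the 28 of the 62 falls that turn direction with it are thus not separate evidence on each miRNA. The array weights did not converge. No filter adjusts over 1881 miRNAs, but how much of the loss this explains was not tested. Nor was the cause tested for the remaining settings.

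Of the lists past the threshold (2), 1 stayed with quantile normalization, cyclic loess, normexp, the scanner software's totals, detection on all 8 arrays, detection on at least 1 array and array weights, 6 passed with no filter, 5 with fry and 0 with an estimated correlation. The list lost was the inflammation-induced one, with shifts and adjusted p of 1.16 (0.0537) under quantile normalization, 1.22 (0.0716) under cyclic loess, 0.851 (0.0524) under normexp, 0.577 (0.309) with the totals, 1.02 (0.244) for detection on all 8, 0.818 (0.0686) on at least 1, 0.338 (0.195) with no filter, 1.15 (0.0934) with array weights and 1.20 (0.462) with an estimated correlation, where the miR-17 to miR-92 clusters had 1.23 (0.480); the ranges over all alternatives with camera were 0.00584 to 0.462 and 9.13e-09 to 0.480. The list of GC-rich late-numbered miRNAs turned to -0.10 with no filter.

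Of the 28 falls that turned with the percentile over all probes, those named among the results above were let-7b-5p (0.11), let-7c-5p (0.24), miR-125b-5p (0.34), miR-128-3p (0.013), miR-130a-3p (0.51), miR-152-3p (0.29), miR-181b-5p (0.12), miR-183-5p (0.29), miR-1906 (0.43), miR-193b-3p (0.082), miR-200a-3p (0.13), miR-200b-3p (0.29), miR-203-3p (0.19), miR-203-5p (0.039), miR-3072-5p (0.18), miR-30a-5p (0.085), miR-30c-5p (0.30), miR-429-3p (0.056), miR-5107-5p (0.00421) and miR-99a-5p (0.15). The scanner software's totals, which leave out undetected probes or give them an error value, turned miR-155-5p (-1.12), miR-17-3p (-0.017), miR-677-3p (-0.46), miR-181b-5p (0.15), miR-183-5p (0.29), miR-467f (2.23), miR-5107-5p (4.99), miR-5112 (0.86) and miR-6908-5p (0.55). Over all named miRNAs and the settings other than leaving out 1 array, 1356 values stayed as they were, 248 lost their call, 56 gained one and 26 turned. Of the list values in these settings 359 stayed, 10 lost, 7 gained and 1 turned. A value past the threshold in neither fit counts as having stayed, whatever its direction.

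With the replicate number as a replicate block, 71 miRNAs changed (28 higher, 43 lower; 27 and 42 shared with the fit without it). The values show no pairing by number, but cannot exclude it. Same-numbered samples deviated from their group means with r of -0.44, 0.20, -0.26 and -0.23, and none correlated best with its own number. In both groups the replicate number is also the slide column of the array, so the block stands for both.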

Other observations

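The tests of neighbouring hairpins and of the arms of 1 hairpin were stated before their results were seen, but the version without the miR-17 to miR-92 list and the version without 1 pair of arms were chosen only after the result was seen.

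Of 4 tested X-linked miRNAs whose hairpins lie within Clcn5, a chloride transporter gene, in the GRCm38.p6 annotation, 3 rose in NcstnΔKC skin; they were picked out after their values were seen and had no test as a set. miR-362-3p was 2.66-fold higher (adjusted p = 0.003), miR-532-5p 2.49-fold (0.00424) and miR-500-3p 1.64-fold (0.0141, a call kept in 6 of the 7 scalings other than the percentile over all probes), each with non-overlapping groups and kept whichever 1 array was left out, though miR-532-5p turned with the scanner software's totals. The probes of miR-500-3p target the X chromosome, 6814874 to 6814888 (mm9). The other, miR-188-5p, differed by -0.75 ± 0.33 (adjusted p = 0.0972), and passed as lower without NcstnΔKC 4.

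Of the 95 changed miRNAs, 37 stand in no list, 11 higher and 26 lower. Among these, again picked out after their values were seen, miR-193a-3p (2.24-fold lower, adjusted p = 0.00166), miR-6360 (2.20-fold, 0.00166), miR-7042-5p (2.58-fold, 0.00238) and miR-8117 (2.62-fold, 0.003) had non-overlapping groups, were lower under all 8 scalings and kept their calls whichever 1 array was left out. The probes of miR-193a-3p target chromosome 11, 79525516 to 79525532 (mm9).

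Clustered miRNAs are often cut from 1 transcript, so neighbours may change together. Some miRNAs with several hairpins were matched by name to 1 of them, as miR-19b-3p to Mir19b-2 and miR-29b-3p to Mir29b-1. Pairs at their other hairpins, such as miR-19b-3p with miR-20a-5p and miR-29b-3p with miR-29c-3p, were therefore left out, and their effect was not tested. The 57 pairs found were of tested miRNAs whose matched hairpins lie within 10 kb. Their mean absolute difference in log2 change was 0.392, against 0.959 for pairs at random (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Of these 57 pairs, 49 lay on the same side of the median. Without the miR-17 to miR-92 list the 41 remaining pairs gave 0.412 (one-sided permutation p = 1e-05, again the smallest possible), with 33 on the same side. This is consistent with co-transcription of miRNA clusters, although near-identical sequences within clusters share signal and can also make neighbours look alike.

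The arms of 1 hairpin were set side by side in the same way. Over 9 pairs of tested arms the mean absolute difference was 0.723, against 0.961 at random (one-sided permutation p = 0.168), with 6 of 9 pairs on the same side of the median. Without the pair of miR-1897-3p, which was detected on 0 NcstnΔKC arrays, and miR-1897-5p, the other 8 gave 0.496 against 0.960 (one-sided permutation p = 0.0239), so the result rests on 1 pair. Whether hairpins or single arms changed therefore stays open.

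Some miRNAs varied more within the normal group than between groups. miR-3960 stood at 3.03, 2.77, 0.01 and 0.11 in normal 1 to 4 and at 1.58, 1.94, 2.10 and 2.48 in NcstnΔKC 1 to 4 on the scaled log2 scale. miR-5126 stood at 2.30, 2.61, 0.35 and 0.49 and at 1.88, 1.85, 1.46 and 1.70. Neither differed between groups by the test (adjusted p = 0.545 and 0.66). The same split of the normal arrays shows over all tested miRNAs. Normal 1 and 2 correlated with r = 0.966 and normal 3 and 4 with r = 0.982, against 0.915 to 0.933 across these pairs. What sets the pairs apart was not tested.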
